A study of Drosophila melanogaster with 6 samples.

How the data were processed

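Total RNA came from male larvae in the third instar, 50 per preparation, with 3 preparations per genotype that the series' design text calls independent. It was extracted with TRIzol and hybridised to single-colour Affymetrix Drosophila Genome 2.0 arrays, per the labels' protocols. Groups were taken from the labels' sample descriptions: roX1 roX2 mutant (3 arrays) and roX1+ roX2- control (3 arrays).

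The deposited values are intensity values per probe set on a linear scale, 1 column per array, and the submitters' processing notes name GCOS 1.2. Per the labels' design text, the authors filtered genes by a perfect match minus mismatch comparison, brought the median of autosomal transcripts to 100 on each array and adjusted X-linked transcripts by the same factor. The algorithm that summarised the probes is not given in the sources used here, and detection calls were not used here. The deposited scale could not be matched to that description. The median over all probe sets was 109, 106 and 106 on the mutant arrays and 102, 102 and 102 on the control arrays, while over autosomal probe sets it was 184, 181 and 180 in the mutant and 167, 164 and 166 in the control. The values are linear and not centred, and between 113 and 169 values per array were at or below 0. Which genes the authors scaled on stays unknown.

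Probe sets were named through a table of the platform annotation, updated through gene IDs to the RefSeq gene table of the Release 6 plus ISO1 MT assembly, which was used only for names, chromosomes and gene order. The probe table can be old. Of 18952 probe sets, 183 were controls, and of the other 18769, 13647 had 1 gene, 402 had several and 4720 had none listed. Of those with 1 gene, 13544 matched by gene ID, 6 by symbol and 85 by an older name, and 12 kept their older symbol. Probe sets with several genes or none entered no named result, so well-known genes without a name in the table were not analysed here.

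Probe sets in the upper 50% by mean log2 signal over all 6 arrays were kept (9384, of which 8165 had 1 gene). This filter replaced detection calls. Values at or below 0 were set to the lowest value above 0. Each gene was represented by its probe set with the highest mean signal, which left 7801 genes. Of 301 genes with over 1 kept probe set, 8 had probe sets that passed in opposite directions (ClC-a, fau, Gfat1, kumpel, Lmpt, Nna1, row and Sarm), and none of these is reported singly. Each array was then multiplied by 1 factor that set the median of kept autosomal genes on chromosomes 2, 3 and 4 to 100. Factors were 0.246, 0.260 and 0.262 for the mutant arrays and 0.280, 0.279 and 0.279 for the control arrays. Signals in the text are on this scale, and no offset was added before taking log2.

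Genes were tested with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, with data handling by data.table (1.17.8), in a fit of all 6 arrays with group as the only term. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. A log2 difference is the mutant mean minus the control mean. The shift of a chromosome is its median log2 difference minus that of chromosomes 2 and 3. The same value per array, taken as deviations from the control mean, was compared by an exact two-sided permutation test, which cannot give a p below 0.1 with 3 against 3. Chromosomes and gene lists were tested against the remaining genes with camera, with an inter-gene correlation preset at 0.01 and again with an estimated one. Shares of falls and rises were compared by Fisher's exact test.

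Named genes followed a rule fixed before the data were examined: all measured MSL complex members, the 8 autosomal genes with the largest rise and the 8 with the largest fall, the 6 X-linked genes with the largest rise and the 6 with the largest fall (passing, and with all mutant arrays on one side of all control arrays), up to 4 genes of smallest p in each list, and the 4 of smallest p on chromosome 4. Of the 119 named genes that passed, 24 had a mean in their lower group under the median probe set (27.9 on the scaled signal), so the size of their difference is uncertain. Beyond those with this limit in the results, they were JIL-1, S-Lap5, CycD, rn, Appl, g and r. bt, apolpp and the members of gene families in the closing section were named after their values were seen. An older name of a list member counted only where it belongs to 1 gene of the RefSeq table, a rule added after the data were seen. The 27 gene lists were also fixed before the data were examined and cover the MSL complex and roX RNAs, heterochromatin and chromosome 4 factors, genes in pericentromeric heterochromatin, tissues (fat body, midgut, muscle, testis, hemocytes, Malpighian tubule, nervous system, imaginal discs, cuticle, glue genes), stage and hormone response (ecdysone response, late larval 71E genes), immunity, heat shock, apoptosis, detoxification, glycolysis, respiratory chain, proteasome, ribosomal proteins, sex determination, and X-linked, Y-linked and Stellate reference genes.

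The fits were tested on simulated arrays of 7801 genes with 200 changed genes. Of 50 genes changed 1.5-fold 82% were recovered, and of 50 each at 2-, 3- and 4-fold all were, with 12 calls among unchanged genes. A simulated X shift of -0.3 was recovered as -0.303 and a chromosome 4 shift of -0.45 as -0.442. Over 20 simulations without change, 3 lists and 4 genes were called. The simulated noise was independent between genes, so these runs do not show how the list test holds where genes vary together. The alternatives tried were 4 other scalings or normalizations (all kept genes, chromosomes 2 and 3 only, quantile, none), no filter and a filter at the upper 33.3%, offsets of 10 and 50, eBayes without trend and with robust estimation, all probe sets or their mean per gene, ratios of mean linear signals, the replicate number as a block, and leaving out each array. A minimum mean signal of 50 was added after the data were seen. A first test of whether X-linked genes fell because of lower signal was run and replaced by the shift in 4 signal classes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.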

Results

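Gene expression was measured in male larvae of Drosophila melanogaster, in the third instar, with mutations in both roX1 and roX2 or in roX2 alone. roX1 and roX2 are noncoding RNAs of the MSL complex, which binds the single X chromosome of males and raises its transcription to match the 2 X chromosomes of females. The mutant group carried the roX1 allele SMC17A together with a roX2 mutation (3 arrays), and the control group was roX1+ and roX2- (3 arrays). Each array held RNA of a separate preparation from 50 larvae, hybridised to a single-colour Affymetrix Drosophila Genome 2.0 array. The comparison asks how X-linked and autosomal expression differ when roX1 is mutated in males that already carry a roX2 mutation. After scaling, 7801 genes were tested, of which 1111 lie on X, 6636 on chromosomes 2 and 3 and 48 on chromosome 4. Arrays of the same group correlated across genes at 0.972 or higher in the mutant and 0.984 or higher in the control, against 0.889 to 0.926 between groups; genes are not independent replicates. Mutant array 1 lay closest to the controls. The number of arrays, 3 per group, limits the precision of every value.

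X-linked genes were lower in the mutant. Of the 1111 X-linked genes, 534 (48.1%) fell and 115 (10.4%) rose, while on chromosomes 2 and 3 falls (1952 genes, 29.4%) and rises (1689 genes, 25.5%) were closer to balance (limma, Benjamini-Hochberg adjusted p under 0.05). The median X-linked log2 difference was -0.29, and the X shift, this median minus that of chromosomes 2 and 3, was -0.27, a 17% lower signal. The shift was nearly equal on the 3 mutant arrays, at -0.28, -0.26 and -0.27 (mean -0.27 ± 0.0081, SD, n = 3), against 0.01, -0.03 and 0.02 on the control arrays (SD 0.028, n = 3). Among passing X-linked genes with all mutant arrays below all control arrays, Btnd fell most (log2 -2.56, SE 0.11, limma adjusted p = 2.92e-05). Cngl (-2.40), yin (-2.33), CG12645 (-2.20), hog (-2.18) and CG15210 (-2.16) followed. Rises on X went against the chromosome's median: CG14205 rose by 3.68 (SE 0.273, adjusted p = 8.78e-05), CG3106 by 2.61, vanin-like by 2.17, CG32603 by 2.12 and Cpr11B, a cuticle protein gene, by 2.07. Alms1a rose by 2.59 as well, but a near-identical neighbouring copy leaves its own level uncertain. The sizes for CG14205, CG3106, Alms1a, Btnd and CG15210 are uncertain, as the mean of their lower group lay under the median probe set (27.9).

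The 3 mutant and 3 control shifts did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest this design allows. Deviations were taken from the control mean, so the control shifts lie near 0 by construction. The test therefore does not treat the groups alike, and its p is only descriptive. Each of the 4 large autosomal arms also gave p = 0.1 in this exact test, which therefore does not set X or chromosome 4 apart from them. Against all other genes, limma's camera gave p = 2.04e-07 for X with a preset inter-gene correlation of 0.01. With an estimated correlation it gave p = 0.00513. The estimated correlation was 0.00862, below the preset one, so correlation between genes does not account for the larger p. The 2 settings of camera therefore differ in more than the correlation. X-linked genes had higher odds of a fall than genes of chromosomes 2 and 3 (odds ratio 2.22, 95% interval 1.95 to 2.53, Fisher's exact test) and lower odds of a rise (0.338, 0.274 to 0.414); genes are not independent replicates in these 2 tests. The 4 large autosomal arms differed from one another by little: 2L lay at -0.03, 2R at 0.02, 3L at -0.04 and 3R at 0.04 relative to the other 3 arms. With an offset of 50 added to the scaled signal before the logarithm the X shift was -0.15, and without mutant array 2 the rises on X numbered 75.

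**Figure D1:**
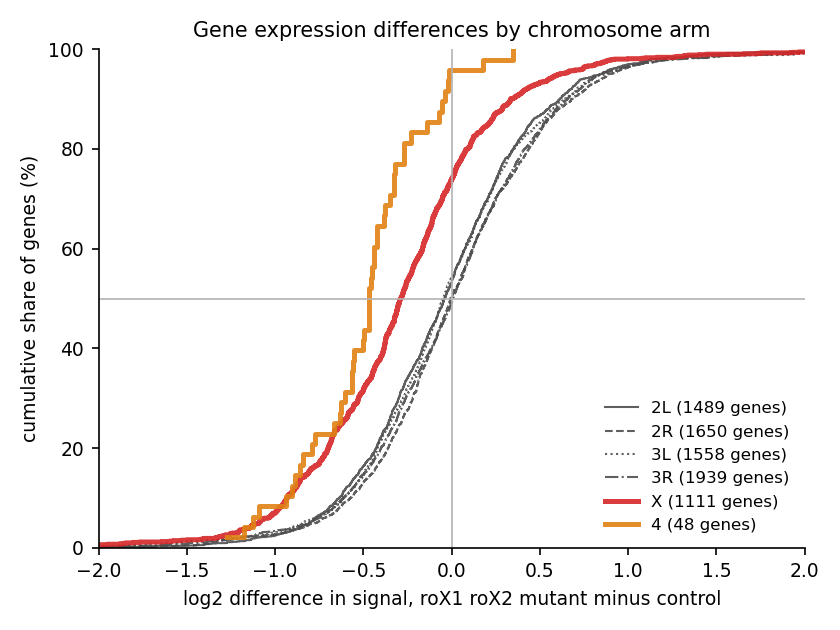
Cumulative share of genes (vertical axis, percent) by log2 difference in signal, mutant minus control (horizontal axis, drawn from -2 to 2), for each chromosome arm. The X curve crosses 50% at -0.29 and the chromosome 4 curve at -0.47, while the autosomal arms 2L, 2R, 3L and 3R cross between -0.05 and 0.01.

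**Figure D2:**
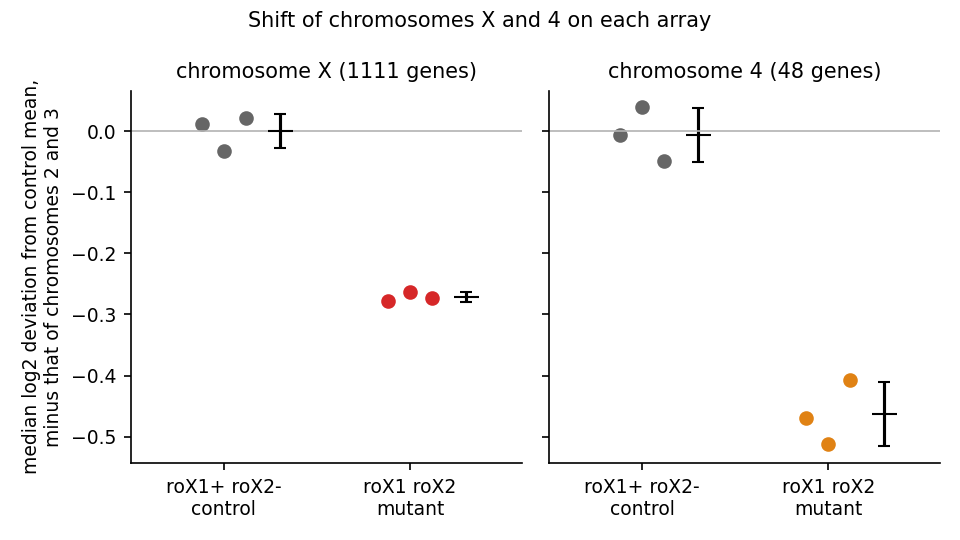
Median log2 deviation of X-linked genes (left) and chromosome 4 genes (right) from the control mean on each array, minus that of chromosomes 2 and 3; points are arrays, and bars give the mean and SD of 3 arrays. Mutant arrays lie between -0.26 and -0.28 for X and between -0.41 and -0.51 for chromosome 4, with control arrays between -0.05 and 0.04.

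The lower signal extended along the whole of X. When the tested X-linked genes were ordered along the chromosome and divided into 10 bins, every bin had a median below that of chromosomes 2 and 3 on all 3 mutant arrays. The bin from Polr3A to Ubr1 was lowest, at -0.39, with 65 of its 111 genes falling. The last bin, which ends with su(f) near the centromere, was least lowered, at -0.15 with 39 falls, and the bin from Zpr1 to CG11756 stood at -0.17. Differences between bins were not tested. From the dimmest to the brightest of 4 signal classes the X shift was -0.26, -0.23, -0.35 and -0.26. Of the 534 X-linked genes that fell, 234 did so by less than 1.5-fold and 77 by at least 2-fold.

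**Figure D3:**
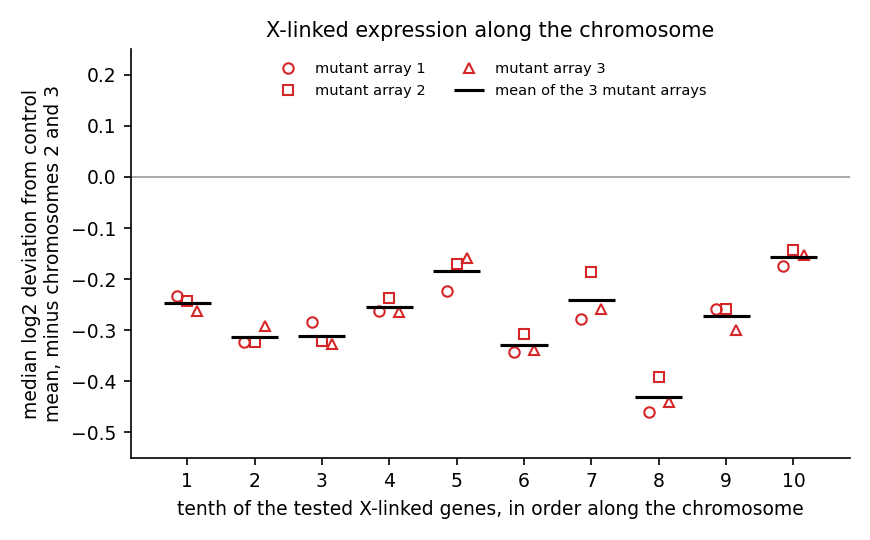
Median log2 deviation of X-linked genes from the control mean, minus that of chromosomes 2 and 3 (vertical axis), in 10 bins of 111 or 112 tested genes in order along X (horizontal axis). Symbols are the 3 mutant arrays and lines their mean; the means run from -0.16 in the last bin to -0.43 in the 8th.

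Chromosome 4, the small and largely heterochromatic autosome, was lower in the mutant by more than X. Of its 48 tested genes, 39 fell and none rose (limma, 0 rises also at an unadjusted p under 0.05), and its shift, its median minus that of chromosomes 2 and 3, was -0.45, a 26.7% lower signal. The shift was -0.47, -0.51 and -0.41 on the mutant arrays (SD 0.052, n = 3) and -0.01, 0.04 and -0.05 on the control arrays (SD 0.044, n = 3). From the dimmest to the brightest of the same 4 signal classes the chromosome 4 shift was -0.74 (8 genes), -0.43 (3 genes), -0.59 (14 genes) and -0.28 (23 genes). The 4 genes with the smallest p were CG32017 (log2 -1.18, SE 0.101, adjusted p = 0.000131), mav (-0.94), which encodes a TGF-beta family ligand, Ephrin (-0.89) and dpr7 (-1.27). ci, the transcription factor of Hedgehog signalling, fell by 0.56, and unc-13, which acts in synaptic vesicle priming, fell by 0.61. bt and apolpp, chosen after their values were seen, did not pass: bt, a large muscle protein gene, stood at 0.18 (adjusted p = 0.448, limma) and apolpp, the apolipophorin precursor of the fat body, at -0.07 (adjusted p = 0.5).

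The exact permutation test of the per-array chromosome 4 shifts gave p = 0.1, again the smallest possible and only descriptive, as for X. The camera test of limma gave p = 1.42e-08 with the preset correlation. This was lost with an estimated correlation (0.192, camera p = 0.0952), a setting that differs in more than the correlation. The odds of a fall were 10.4 times those of chromosomes 2 and 3 (95% interval 4.94 to 24.4, Fisher's exact test). Genes are not independent replicates in this test either, so the interval is only descriptive. Without mutant array 1 the rises on chromosome 4 numbered 1, and whether the chromosome 4 shift differs from the X shift was not tested.

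Across all chromosomes 4330 genes changed, 1805 up and 2525 down (limma, Benjamini-Hochberg), so that rises made up 41.7% of the calls. Without rescaling, the median log2 difference of all genes was 0.07 in place of -0.06, a move of 0.13, and the split turned to 2406 rises and 1709 falls (58.5% rises), with 1274 falls and 2242 rises on chromosomes 2 and 3. On these chromosomes the balance also turned with all-gene scaling (1725 falls, 1890 rises) and quantile scaling (1752 falls, 1863 rises), so directions are given relative to the autosomal median. On chromosomes 2 and 3, 222 genes rose and 190 fell by at least 2-fold. The autosomal genes with the largest fitted rises were Mal-A3, a maltase gene (log2 4.49, SE 0.612, adjusted p = 0.000687), CG15534 (4.41), the cuticle protein gene Cpr47Ec (4.25), the trypsin gene lambdaTry (3.77), CG31233 (3.30), CG5550 (3.23), CG9757 (3.23) and Sodh2, a sorbitol dehydrogenase gene (3.08). The largest autosomal falls were in lncRNA:CR33948 (-3.56, SE 0.781, adjusted p = 0.00577), CG14664 (-3.15), CG12951 (-3.09), the drosomycin-like gene Drsl5 (-2.65), CG13314 (-2.59), CG13722 (-2.46), slbo, a C/EBP transcription factor gene (-2.27), and Achl (-2.21). The control means of Mal-A3 (13.8), CG15534 (7.58), Cpr47Ec (15.9), lambdaTry (12.2), CG31233 (25.4) and CG5550 (9.34) and the mutant means of CG13314 (19.7) and Achl (23.3) lay under the median probe set (27.9), so their exact sizes and order are uncertain. With an offset of 50 the Mal-A3 rise was 2.27, CG15534 1.86 and CG9757 2.61. Sodh2, CG12951 and slbo, whose lower group means lay above that limit, shrank to 1.97, -1.88 and -1.20. On mutant arrays 2 and 3, CG12951 (17.7 and 23.6) and slbo (15.2 and 23) lay under it. Sodh2 lay close to it on control arrays 2 and 3 (27.6 and 27.0), so these 3 sizes are also uncertain. lncRNA:CR33948 and CG14664 stood at -2.69 and -2.65. Drsl5 did not pass without control array 2 (adjusted p = 0.055) or with robust eBayes (0.0515). Mal-A3 and CG14664 differed less on mutant array 1: the scaled Mal-A3 signal was 117 there against 348 and 380 on the other 2 mutant arrays and 5.68 to 26.8 in controls, and that of CG14664 was 330 against 51.0 and 120, with 741 to 1392 in controls.

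No probe set carries the name roX1 or roX2 in the probe table used, so both RNAs were not analysed here and the labelled genotype was not checked at its own locus. The list of MSL complex, partner and roX genes held 12 names. Of these, 9 matched a probe set and 8 were measured. The complex gene mle was not among the 8, so the complex was not covered in full. The measured genes of the MSL complex and its partners showed small differences. Of the 8 measured, JIL-1, a histone kinase enriched on the male X, fell by 0.63 (SE 0.142, adjusted p = 0.00648, limma), and 7 did not pass. mof, the X-linked acetyltransferase of the complex, stood at -0.37 (adjusted p = 0.0532), msl-2 at 0.24 (0.198), msl-3 at 0.23 (0.126), msl-1 at 0.04 (0.788), Clamp at -0.12 (0.19), Iswi at 0.13 (0.179) and Su(Tpl) at 0.29 (0.109). mof passed without control array 2 (log2 -0.52, adjusted p = 0.00901) and with eBayes without trend (0.0489), Su(Tpl) passed without mutant array 3 (0.39, adjusted p = 0.0447), and msl-3 (0.0277), Su(Tpl) (0.0454) and Iswi (0.0468) passed without rescaling. The median of the list was 0.08 and its mean -0.03, and camera placed it upward with adjusted p = 0.804 (0.834 with an estimated correlation). The median ran from 0.04 (without control array 2) to 0.11 on leaving out 1 array and from 0.04 (every probe set) to 0.21 (without rescaling) over the other alternatives.

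Of 27 gene lists fixed before the data were examined, 24 had at least 3 measured members and were tested with camera. With the preset correlation 3 passed, glycolysis, testis and ecdysone response, and with an estimated correlation none did (0 also at an unadjusted p under 0.05). The number passing was 8 without mutant array 1 and 6 without control array 1. Of the 10 ways to split the 6 arrays 3 against 3, 9 called at least 3 lists, the real split included. The count of passing lists therefore does not set the real groups apart from mixed ones. Estimated correlations of glycolysis, testis and ecdysone response were 0.487, 0.326 and 0.437, against the preset 0.01. As the 2 settings differ in more than the correlation, these values need not be the only reason that the calls were lost. Counts of members are over all genes tested; adjusted over the list alone they were equal unless another count is given.

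Of 11 measured genes of glycolysis, 10 rose, among them Gpdh1, the cytosolic glycerol-3-phosphate dehydrogenase (log2 1.52, SE 0.126), Pfk, phosphofructokinase (1.46), Pgi (1.15) and Eno, enolase (0.64), and the list's adjusted p was 0.000164 (camera), or adjusted p = 0.81 with an estimated correlation. Its median was 0.45 on mutant array 1 and 0.77 and 0.70 on the other 2. Fat body genes also leaned up: 8 of 13 rose and 2 fell, led by the lipid synthesis genes FASN1, fatty acid synthase (2.35), and ACC, acetyl-CoA carboxylase (1.75), with Lsd-2, a lipid droplet protein gene, at 0.57 and a fall in Fbp1, a larval serum protein receptor gene (-0.26, lost without rescaling). This list had adjusted p = 0.0739 (camera; 0.81 with an estimated correlation), and 0.0293 without mutant array 1, within 0.0293 to 0.119 over all alternatives. Of 68 genes of the respiratory chain and ATP synthase 51 did not pass, 13 rose and 4 fell (13 and 3 adjusted over the list alone), with rises in RFeSP (0.88), Cyt-c1 (2.01-fold), ND-42 (0.73) and ATPsyngamma (0.56). The adjusted p of the respiratory list was 0.0686 (0.816 with an estimated correlation), and 0.00234 without mutant array 1, within 0.00234 to 0.172 over all alternatives. Of its 10 X-linked members 3 fell, against 1 fall and 13 rises among 57 on chromosomes 2 and 3. Its median was -0.07 on mutant array 1 and 0.14 and 0.08 on the others.

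Testis genes rose in part. Of 32 measured, 17 rose and 5 fell (17 and 6 adjusted over the list alone), and the list passed camera (adjusted p = 0.015, or adjusted p = 0.81 with an estimated correlation). The sperm leucyl aminopeptidase genes S-Lap8 (log2 1.01), S-Lap5 (1.22) and S-Lap2 (0.78) rose, while Taf12L, a testis-specific TAF gene, fell by 0.72. With no signal filter the testis call was lost (adjusted p = 0.0553, the highest of all alternatives, from 0.007). The testis median was 0.36, 0.21 and 0.20 on the mutant arrays. In muscle 7 of 13 genes rose and 1 fell (adjusted p = 0.0606, 0.816 with an estimated correlation), with sls, the titin-like gene, at 1.97, Zasp52 at 0.98 and Prm, paramyosin, at 0.75, and Zasp66 at -0.48. The muscle list had adjusted p = 0.00188 without mutant array 1 and 0.041 without control array 1, within 0.00188 to 0.115 over all alternatives. The muscle median was 0.26 on mutant array 1 and 0.67 and 0.78 on the other 2. Of the 12 Malpighian tubule genes, 3 rose, Fst (0.44), Cyp6a18 (0.97) and Irk1 (0.51), and Irk3 stood at 0.34 without passing (adjusted p = 0.0589), though it passed without mutant array 1 (0.0229) or control array 1 (0.0312), with all-gene (0.0365) or quantile scaling (0.0261), without rescaling (0.0136) and with eBayes without trend (0.0465). The Malpighian tubule list had adjusted p = 0.09 (0.81 with an estimated correlation), and 0.0282 with quantile scaling, within 0.0282 to 0.188 over all alternatives. Hemocyte genes split, with 2 of 14 rising, Nplp2 (2.68) and Hml (0.75), and 3 falling, among them the phagocytic receptor genes eater (-0.67) and crq (-0.44), at list adjusted p = 0.231 (0.81 with an estimated correlation).

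Of 15 measured ecdysone response genes, 10 fell, 5 did not pass and none rose (0 at an unadjusted p under 0.05, limma), including the nuclear receptor gene Hr39 (log2 -0.86), the X-linked transcription factor gene br (-0.79), the ABC transporter gene E23 (-1.27) and ImpE3 (-1.54). The list passed camera (adjusted p = 0.0337) but not with an estimated correlation (adjusted p = 0.81 with an estimated correlation); the call was also lost without mutant array 2, mutant array 3 or control array 3, at adjusted p = 0.0616, 0.0713 and 0.0577, and with no signal filter, at 0.0592 (range over all alternatives 0.00181 to 0.0713). Its median was -0.32 on mutant array 1 and -0.59 and -0.49 on the others. Glue genes, the salivary secretion that ecdysone controls, fell in 7 of 10 cases and rose in 2 (adjusted p = 0.215, 0.816 with an estimated correlation), with falls in Sgs4 (-0.68) and Eig71Ee (-0.41). Sgs4 was the brightest probe set on all 3 control arrays, where a ceiling of the signal was not excluded, so its exact size is uncertain. Sgs3, Sgs5, Sgs7 and Sgs8 were also bright, with control means of 2640 to 2906, and their falls were small (log2 -0.15 to -0.23). Near a ceiling the lower scaling factors of the mutant arrays alone would give such falls, and this was not excluded. The glue list's median, -0.16, was -0.03 with quantile scaling and -0.04 without rescaling. ng1 (1.65) and ng2 (-1.34) went opposite ways but are near-identical copies, so their separate levels are uncertain. The 8 late larval 71E genes on the array did not reach the signal filter, and this list has no value. Of 6 cuticle genes 2 fell, Pcp (-1.11) and Ddc, dopa decarboxylase (-1.14), and 2 rose, Lcp9 (1.22) and Lcp65Aa (0.89), at list adjusted p = 0.827 (0.834 with an estimated correlation). The cuticle median, -0.03, turned to 0.10 without rescaling and to 0.02 and 0.01 with all-gene and quantile scaling. It ran from -0.11 to 0.51 on leaving out 1 array (0.51 without control array 1) and from -0.30 to 0.10 over the other alternatives. The calls of Lcp9 and Lcp65Aa were lost when single arrays were left out: without mutant array 2 their adjusted p was 0.0858 and 0.134, without mutant array 3 0.0703 and 0.124, without control array 2 0.083 and 0.0998, without control array 3 0.0867 and 0.132, and Lcp65Aa had 0.0524 without control array 1.

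**Figure D4:**
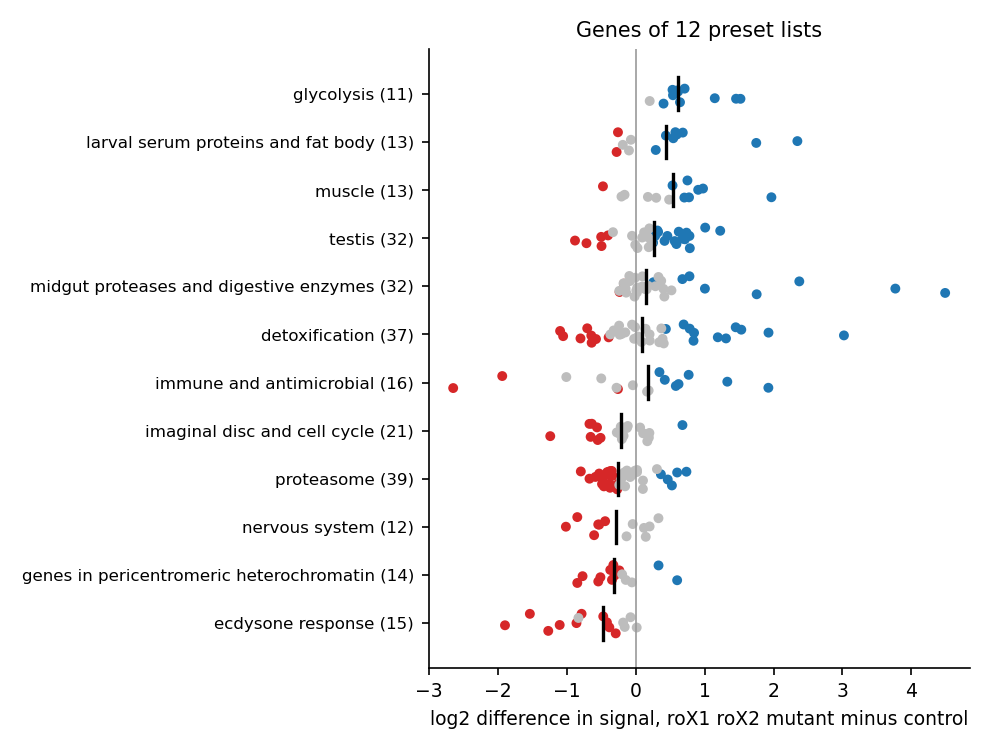
Log2 difference in signal, mutant minus control (horizontal axis), of each measured gene in 12 of the gene lists (rows, number of genes in parentheses). Blue points rose, red points fell and grey points did not pass; black bars are list medians, from 0.61 for glycolysis to -0.47 for ecdysone response.

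Digestive enzyme genes held large rises, and detoxification genes held large rises and falls. Of 32 midgut protease and digestive enzyme genes 8 rose and 2 fell (7 and 2 adjusted over the list alone), with the serine protease gene Ser6 (log2 1.75) and the maltase gene Mal-A4 (2.37) next to Mal-A3 and lambdaTry, at list adjusted p = 0.0686 (0.816 with an estimated correlation). The midgut list had adjusted p = 0.00234 without mutant array 1 and 0.041 without control array 1, within 0.00234 to 0.258 over all alternatives. Of 37 detoxification genes 11 rose (10 adjusted over the list alone) and 8 fell, at adjusted p = 0.341 (0.834 with an estimated correlation). The cytochrome P450 genes Cyp6a2 (3.02) and Cyp6w1 (1.93) rose, while Cyp6d2 (-1.05) and Cyp6d5 (-1.10) fell. The sizes for Cyp6a2, Ser6 and Mal-A4, and for PGRP-SB1 among the immune genes, are uncertain, as the mean of their lower group lay under the median probe set. The medians of these lists on mutant array 1 were -0.02 and -0.19, against 0.24 and 0.22 on array 2 and 0.19 and 0.24 on array 3. Of 16 immune and antimicrobial genes 7 rose and 3 fell, with PGRP-LB (0.62), the NF-kappaB genes Rel (0.77) and dl (0.42) rising and PGRP-SB1 falling (-1.94). The immune list's median was 0.17, its mean -0.02 and its test upward at adjusted p = 0.215 (0.81 with an estimated correlation). Of 12 heat shock genes 3 rose and 3 fell (2 and 2 adjusted over the list alone), with Hsc70-2 (1.11) and the mitochondrial Hsc70-5 (0.46) rising and Hsc70-3 (-0.44) and Hsp27 (-0.40) falling, at adjusted p = 0.586 (0.834 with an estimated correlation). The Hsp27 call was lost without mutant array 2 (adjusted p = 0.0555), control array 2 (0.0662) or control array 3 (0.0628), with quantile scaling (0.101) and without rescaling (0.113). The heat shock median, 0.01, ran from -0.11 (without mutant array 1) to 0.08 on leaving out 1 array and from -0.08 (every probe set) to 0.13 over the other alternatives.

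None of the proteasome, ribosomal protein, imaginal disc, nervous system and apoptosis lists passed camera. Of 39 proteasome genes 20 fell and 5 rose (21 and 5 adjusted over the list alone), led by Prosbeta4 (log2 -0.80), Prosalpha4 (-0.59) and Prosbeta3 (-0.49), at list adjusted p = 0.0686 (0.816 with an estimated correlation). The proteasome list had adjusted p = 0.0227 without mutant array 1 and 0.041 without control array 1, within 0.0148 to 0.157 over all alternatives. By a division chosen after the data were seen, among the 26 members that are not T or R copies, 16 fell and 1 rose (median -0.36), while the 13 T and R copies, such as Prosbeta5R1, which rose by 0.73, split 4 and 4 (median -0.06). Of 40 cytosolic ribosomal protein genes 15 fell and 2 rose, but adjusted over the list alone 3 fell and 1 rose; RpS19b fell by 0.61, RpS27A by 0.20 and RpS28b by 0.22, and RpL3 rose by 0.32 (list adjusted p = 0.0701, 0.816 with an estimated correlation). RpS27A and RpS28b did not pass with quantile scaling (adjusted p = 0.185 and 0.0797) or without rescaling (0.172 and 0.0796). Their control means, 2763 and 2806, lay in the range of the bright glue genes. Falls given by a ceiling and the lower mutant scaling factors were not excluded here either. The ribosomal median was -0.19 on mutant array 1, which had the lowest scaling factor, and -0.08 and -0.11 on mutant arrays 2 and 3. The ribosomal list's median, -0.13, was -0.02 with quantile scaling (adjusted p = 0.944) and -0.01 without rescaling (0.703), within adjusted p of 0.0522 to 0.944 over all alternatives. Of 21 imaginal disc and cell cycle genes 7 fell and 1 rose (adjusted p = 0.286, 0.816 with an estimated correlation), with ci on chromosome 4, CycD on X (-1.24) and rn (-0.66) falling and the replication gene dup rising (0.68); the list's median was -0.22, and 0.08 with the upper 33.3% of probe sets kept, the highest of all alternatives. Of 12 nervous system genes 6 fell and none rose (0 at an unadjusted p under 0.05, limma), including Snap25 (-0.85), the X-linked Appl (-1.02), unc-13 on chromosome 4 and nrv3 (-0.55), at list adjusted p = 0.286 (0.81 with an estimated correlation). Of 12 apoptosis and DNA damage genes 4 fell and 1 rose, and the apoptosome genes Dark (-1.30) and Dronc (-0.90) and the TNF gene egr (-0.34) fell while the inhibitor gene Diap2 rose by 0.57 (list adjusted p = 0.814, 0.834 with an estimated correlation). The apoptosis median, -0.10, was 0.03 without rescaling and ran from -0.13 to -0.02 on leaving out 1 array. The egr call was lost without rescaling (limma adjusted p = 0.0948) and without control array 1 (0.0652) or 2 (0.0704). Medians on mutant arrays 1, 2 and 3 were -0.19, -0.27 and -0.36 for the proteasome list, -0.12, -0.20 and -0.25 for imaginal discs and -0.22, -0.24 and -0.36 for the nervous system.

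Genes with a chromatin connection to chromosome 4 or heterochromatin were examined as 2 lists. Pof, whose protein coats chromosome 4, rose by 0.76 (1.70-fold, SE 0.0867, adjusted p = 0.000316, limma). Of the other 6 measured factors, HP1b (log2 -0.37), HP4 (-0.25) and HP1a (-0.20) fell; the list's median was -0.04, its mean 0.03 and its test upward at adjusted p = 0.814 (0.834 with an estimated correlation). The median turned to 0.08 without rescaling and was above 0 with all-gene and quantile scaling. It ran from -0.04 to 0.05 on leaving out 1 array (0.05 without control array 1) and from -0.05 to 0.10 over the other alternatives. These 3 falls were weakly held: without rescaling HP1b, HP4 and HP1a had adjusted p = 0.102, 0.305 and 0.447. HP1b was lost without control array 3 (0.0537), HP4 without mutant array 1 (0.0504), 2 (0.11) or 3 (0.0794) or control array 1 (0.133) or 2 (0.106), and HP1a without mutant array 1 (0.0578), 2 (0.119) or 3 (0.0601) or control array 2 (0.125) or 3 (0.132). Of 14 genes in pericentromeric heterochromatin 9 fell and 2 rose (10 and 2 adjusted over the list alone), with falls in Cht10 (-0.77), Snap25 (-0.85), p120ctn (-0.51) and Haspin (-0.54). That list's adjusted p was 0.0701 (0.81 with an estimated correlation), and its median was -0.27, -0.39 and -0.27 on the mutant arrays.

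Among 7 eye pigment, body color and housekeeping reference genes, of which 6 are X-linked, cm (log2 -0.70), g (-0.78) and ras (-0.95) fell and r rose by 0.50, a call lost without mutant array 1 (adjusted p = 0.0968), mutant array 2 (0.123) or control array 2 (0.116) and with no filter (0.052; list adjusted p = 0.252, 0.816 with an estimated correlation). The median of this list was -0.18 on mutant array 1 and -0.70 and -0.49 on the other 2. In the sex determination list ix (-0.62) and the X-linked Sxl (-0.52) fell, and tra2 (-0.16, adjusted p = 0.174, limma) and tra (-0.06, adjusted p = 0.629) did not pass (list adjusted p = 0.252, 0.81 with an estimated correlation). ARY, the only measured gene of the Y-linked list, stood at -0.14 (adjusted p = 0.308), and Ssl, the only one of the Stellate list, at -0.03 (adjusted p = 0.82).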

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

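The tests of matched signal on chromosome 4, of neighbouring genes, complex members and sequence variants on X and of compressed signal on mutant array 1 were chosen after the result was seen, as were the bound for stretches on chromosome 4, the leaving out of copies in the complexes, and the bin form of the neighbour test on X, which replaced the share of stretches given with it.

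Probe sets outside the named genes also held differences. Of 951 kept probe sets with no gene listed, 163 rose and 301 fell, and of 268 with several genes, 66 rose and 85 fell (limma, Benjamini-Hochberg). Among those with no gene listed, 2 rose from control means of 12.3 and 14.9 to mutant means of 187 and 206, and 2 fell from 166 and 83.8 to 22.4 and 13.5 (scaled signal); the lower means lie under the median probe set, so no fold is given. The probe set of CG6788, an X-linked gene, had a mean deposited signal of 23.03 in the mutant (SD 79.9, n = 3) and -1454 in the control (SD 209, n = 3), far below 0 on all 3 control arrays, and entered no test. A signal this far below 0 is no level of expression, and neither a fault of the probes nor a strain variant under them was tested for it.

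For the fall of X-linked genes, neighbours that move together could lower a stretch of any chromosome, but all 10 bins of X had a median among the lowest 5% of 6196 autosomal stretches of 111 neighbouring genes; 4.45% of those stretches, which overlap, were as low as the least lowered bin. If members of a broadly expressed complex moved alike, changed tissue or stage makeup alone would not separate its X-linked members from autosomal ones. Within the ribosomal, respiratory chain and proteasome lists the 17 X-linked members lay at -0.272 relative to the 129 autosomal ones. The permutation p was 1e-04, the smallest that 10000 reassignments can give. With 3 X-linked and 41 autosomal members whose symbol marks a copy left out, the value was -0.33 (permutation p = 2e-04). The lists then differed: -0.39 for 10 X-linked respiratory members, -0.25 for 3 of the proteasome and 0.07 for the 1 ribosomal member. Of the 3 X-linked members left out, RpS28b and RpL37-1 were brighter than RpS28-like and RpL37-2 (control means 2806 and 2052 against 50.25 and 159.6). RpS28b and RpL37-1 stood at only -0.22 and -0.19, so the lower value without them adds no support. The premise was not tested, and autosomal members did not all move alike. Of 57 respiratory members on chromosomes 2 and 3, 13 rose and 1 fell, with RFeSP at 0.88 and ND-15, which did not pass, at -0.23. Genes are also not independent replicates in this permutation, so its p is only descriptive and makeup stays open. Sequence variants on X between strains would lower only part of the probe sets, yet the upper quartile of X lay below the autosomal one by 1.07 times the difference of the medians, which argues against variants as the whole cause. Loss of roX1 function stays as the hypothesis that the design names, and other differences between the 2 strains' X chromosomes were not tested.

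On chromosome 4 the median of -0.47 was matched by 0% of 10000 lists of chromosome 2 and 3 genes of like mean signal (lowest -0.32). Of 6448 autosomal stretches of 48 neighbouring genes, 0% were as low, with a one-sided 95% upper bound of 2.21% over 134 stretches without overlap, although the lowest came close at -0.46. That lowest stretch, from CG4839 to lft on 2L, held 34 falls and 4 rises. A roX1-dependent effect on chromosome 4 may remain as a hypothesis, beside makeup and strain differences, which were not tested for this chromosome.

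Mutant array 1 showed smaller autosomal differences than the other 2 mutant arrays, with a slope of 0.747 against their mean and 370 autosomal genes at least 2-fold from the control mean, against 521 and 486. Compression of the whole array would also shrink X, but its X shift was 1.04 times that of the other 2 and its chromosome 4 shift 1.02 times. Of the 9 lists that moved by at least 0.3 in the other 2 arrays, 9 lay closer to the controls on mutant array 1, but the lower slope gives this whatever its cause. Testis genes, whose smaller shift kept them out of that count, lay farther from the controls there (0.36, against 0.21 and 0.20). A smaller stage or makeup difference in that preparation stays open, as this count cannot decide it.

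The 10 splits of the 6 arrays are too few for a share under 0.05. The real split called 4330 genes, 649 on X and 39 on chromosome 4, and the highest of the other 9 called 0 in each case (limma; up to 292 genes at an unadjusted p under 0.05 against 4776 in the real split), so 1 of 10 gave as many. Each other split mixes mutant and control arrays on both sides, so a difference between the groups adds to its residual spread. Few gene calls there are therefore built in and give no reference for the real count. For gene lists 9 of 10 splits called as many as the real 3, the highest 12 in the split that put mutant array 1 with control arrays 2 and 3; the reason was not tested.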

How the results depend on the processing

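The signal filter at a mean of at least 50 was chosen after seeing the data. No named gene or list that passed changed direction, but the balance of rises and falls turned with signals as deposited (2406 and 1709), on chromosomes 2 and 3 also with all-gene and quantile scaling, and the medians of 5 lists that passed under no alternative changed sign (cuticle, heat shock, apoptosis, imaginal disc, and heterochromatin and chromosome 4 factors). Of 357 values of main results under alternatives 346 stayed within 1.5 times or on the same side of the threshold and 11 moved; of 2672 values of named genes 55 lost and 12 gained a call, and of 502 values of lists 5 lost and 18 gained one. The X shift ran from -0.29 to -0.15 and that of chromosome 4 from -0.46 to -0.35, and from -0.30 to -0.25 and -0.48 to -0.43 on leaving out 1 array. The number of lists passing was 9 with quantile normalization, 5 with signals as deposited and 1 with no filter, against 3. Signals as deposited gave 1274 falls on chromosomes 2 and 3. With the upper 33.3% of probe sets kept, 329 X-linked genes fell and 69 rose, 398 in all, from fewer genes tested. Leaving out 1 array gave 2 to 8 lists, the highest without mutant array 1 (6 without control array 1), 0 to 1 rises on chromosome 4 (1 without mutant array 1) and 75 to 127 rises on X (75 without mutant array 2). The cause was not tested. The added filter tested 6067 genes and gave 1418 rises and 2041 falls. Signal over background limits genes near the filter, whose log2 differences an added offset shrinks by construction.

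Replicate numbers gave no sign of pairing, as deviations of mutant and control arrays with the same number correlated at -0.342, -0.0644 and -0.385. Between different numbers the correlations ran from -0.358 to 0.508. Deviations centred on 3 arrays per group depend on one another, so these values cannot exclude pairing. With the number as a block 1529 genes rose and 2166 fell, 3665 of them shared with the fit without the block, and 6 named genes no longer passed (Lcp9, egr, r, Lcp65Aa, HP4 and HP1a).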

Other observations

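The tests of families, the genes named from them and the autosomal stretches were chosen after the data were seen; 96 families of at least 5 genes with a shared symbol stem were tested. Alkaline phosphatase genes rose: 7 of 8 tested Alp genes rose and 1 fell, with Alp8 (log2 2.34), Alp10 (2.33), Alp9 (2.29) and Alp4 (2.05) highest, and this was the 1 family that passed camera (adjusted p = 0.0128, or adjusted p = 0.83 with an estimated correlation). Its median was 1.29 on mutant array 1 and 1.73 and 1.74 on the others. Acyl-CoA binding protein genes also held large rises, with 5 of 6 rising, among them Acbp4 (5.66-fold) and Acbp6 (log2 2.17), while Acbp1 fell by 0.87 (family adjusted p = 0.134, 0.83 with an estimated correlation). Of 9 tubulin tyrosine ligase-like genes 5 rose and 1 fell, with TTLL3B at 0.84 (family adjusted p = 0.175, 0.83 with an estimated correlation).

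Genes with Tsp symbols, mostly tetraspanins, fell in 19 of 26 cases and rose in 1, with Tsp39D (log2 -1.02) and the neighbours Tsp42Er (-0.88), Tsp42Ei (-0.80) and Tsp42Ej (-0.80) among them (family adjusted p = 0.0779, 0.83 with an estimated correlation). Mitochondrial ribosomal protein genes fell too, 27 of 44 mRpL genes and 15 of 25 mRpS genes, with 2 and 3 rises; several of the strongest are X-linked, such as mRpS14 (-1.02), mRpL3 (-0.93) and mRpL33 (-0.91). Their family medians were -0.34 and -0.30 (adjusted p = 0.0963 and 0.175, both 0.848 with an estimated correlation), and -0.46 and -0.36 on mutant array 1. All of these family medians kept their sign under the 4 other scalings and normalizations.

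On 3R the lowest stretch of 48 neighbouring genes ran from CG31115 to CG31436 with a median of -0.45, 30 falls and 6 rises, and on 2R from MFS17 to CG14591 with a median of -0.31, 31 falls and 4 rises.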
